A study of Arabidopsis thaliana with 14 samples.

How the data were processed

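Parallel analysis of RNA ends (PARE) captures the 5' ends of RNA molecules that carry a 5' monophosphate, which are mostly intermediates of RNA decay and products of cleavage, as short sequence tags. Per the labels' protocols, the 14 libraries were made from total RNA of Arabidopsis thaliana accession Col-0 with a published PARE protocol. The deposited files hold, for each library, every distinct tag sequence with its raw read count, without any position in a genome. Trimming, aligner and genome build are not given in the sources used here. In 10 libraries the authors deposited tags of 20 and 21 nt only. The 4 files of the 12-day seedlings also hold shorter and longer tags, and there 85.5% to 94.1% of the reads were 20 or 21 nt. Only tags of these lengths were used, and each was reduced to its first 20 nt. The library totals at these lengths ran from 35232571 to 50502966 reads.

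No genome or transcript sequence was used here, so tags were not assigned to genes. Overlapping tags were instead assembled into contigs, which stood in for genes in every test. A 20-mer entered the assembly if it occurred in at least 2 libraries and was not taken as a read error, which was any 20-mer with a neighbour at 1 mismatch and 50 times its reads. The tags were joined in a de Bruijn graph with their 19-mers as nodes. Weak side paths were removed, and dead ends were then joined by overlaps of 17 down to 15 nt where the match was unique both ways. This gave 65357 contigs of 100 nt or more with a median length of 165 nt and a longest length of 2735 nt. One gene can lie on several contigs, so counts of contigs are not counts of genes. Ribosomal, transfer and organelle RNA, which the plan would have left out, could not be recognised and stayed in. Footprints of exon junction complexes upstream of exon junctions, the subject of the series title, and the gene lists of the plan need gene models and were not analysed here.

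Reads per contig were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, filterByExpr, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment at 0.05. Each experiment was fitted on its own: the 6 libraries of 10-day seedlings, the 4 of 12-day seedlings and the 4 of flowers. Standard errors of log2 fold changes came from the quasi-likelihood F statistic. Values per contig are given as CPM, the read count scaled to the normalised total of reads on contigs. The plan fixed the contigs the text could name as the 10 largest rises and the 10 largest falls per comparison among contigs past the threshold with a mean of 5 CPM or more and no overlap between the groups. Because the files do not pair tags with gene names, at most 2 that rose and 2 that fell are named per comparison in Results, by a contig label assigned here. The last section also names contig c7464 and gives c6385 and c21615 for another comparison. The tag with the most reads on a contig is shown only where every library of a wild-type plant held 1 CPM or more of that contig. Where a group had 0 reads, the fold is a lower bound against 3 reads over the group, which covers counting error only. It uses the mean of the other group scaled to contig reads. The bound therefore need not hold for each library or when scaled to all reads.

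The edgeR step was tested on simulated counts with the means, dispersions and library sizes of the real libraries, with 50 features changed at each fold. In the 10-day design the changes were put into xrn4-6 only. With so few features changed the adjusted threshold is strict. The shares called therefore do not carry over to fry1-6 and cycloheximide, where 22.2% and 51.1% of the contigs were called in the real libraries. In the 10-day design 0% of 2-fold changes, 24% of 4-fold, 88% of 8-fold and 96% of 16-fold changes were called, and 6.31% of all calls were unchanged features. In the 12-day design the shares were 2%, 84%, 100% and 100%, and 8.92% of calls were unchanged features. In the flower design they were 2%, 60%, 98% and 100%, and 21.2% of calls were unchanged features, so the share of false calls there was above the nominal 5%. The 8-fold and 16-fold changes were added after the first simulation, which held only the smaller folds, recovered none in the 10-day design.

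Open reading frames of 100 codons or more were found on 10088 contigs, and on 3411 of these the frame ended in a stop codon. The stop codon peak is the share of 5' ends at -50 to -1 from the first nucleotide of the stop codon that lay at -17 and -16, where even spacing would give 4.0%. The reading frame share is the share of 5' ends within the open frame, leaving out 50 nt at each end, that lay in the frame of position -17. Position -16, the other peak position, lies in the next frame, which this share does not count. Both shares are means over contigs with a mean of 10 or more such reads. Groups were compared with two-sided exact permutation tests of the library values. With 2 libraries against 2 such a test cannot give p under 0.333.

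Cleavage sites of microRNAs (miRNAs) were sought on all contigs of 40 nt or more by complementarity to 26 miRNA sequences, listed from general knowledge, with a score of 5 or less (a mismatch counts 1 and a G:U pair 0.5) and no mismatch opposite miRNA nucleotides 10 and 11. A site was kept if the 5' end that cleavage there would leave was the highest position within 50 nt and held 10 or more reads over the 14 libraries, and reads within 1 nt were counted. This left 103 sites, against a mean of 26.2 for 10 sets of shuffled miRNAs. With a score of 4 or less there were 43 sites against 2.60. Some sites with a score above 4 therefore are chance matches. The reads used to keep a site include those of the mutants and of cycloheximide, so a site high in 1 group only could be kept for that reason. Sites entered the edgeR fits as features of their own, and the list of sites was tested with camera in limma 3.58.1 at a preset correlation of 0.01.

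The groups, the comparisons, the edgeR test, the miRNA list, the rule for naming and most alternatives were fixed before the data were examined. The assembly and its settings, the use of contigs for frames and stop codons, and the local-peak rule for miRNA sites, the last of 3 versions of the search, were chosen afterwards, when shares of assembled reads, frame and stop values and miRNA counts per library had been seen but no edgeR fit had been run. The alternatives were DESeq2 1.42.0, other filters and units, a replicate block, a fit of all 14 libraries, each library left out in turn, another assembly and another scaling. The labels do not say that replicates came from separate plants, so p-values measure only the spread between these libraries. Replicates of each group differed by far more than counting noise (chi-square per contig 25.7 to 49.4), so no library was counted as a duplicate. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0 did the other computations.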

Results

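The 5' ends of RNA decay intermediates were profiled in 7 groups of 2 libraries each. Wild-type Col-0 seedlings aged 10 days were compared with seedlings of xrn4-6 and fry1-6. XRN4 is the cytoplasmic 5'-to-3' exoribonuclease of plants, and FRY1 is a phosphatase that removes an inhibitor of the XRN exoribonucleases. Seedlings aged 12 days were treated for 6 h with 10 µg/ml cycloheximide, an inhibitor of translation elongation, or mock-treated. Flowers of plants aged 4 to 5 weeks, moved from 22 °C to 28 °C, came from wild type and smg7-1, a mutant of a factor of nonsense-mediated mRNA decay. Each library held 35232571 to 50502966 reads of 20 or 21 nt. In wild-type, xrn4-6, mock, cycloheximide and flower libraries 52.9% to 67.1% of these reads lay on contigs, but in fry1-6 only 35.4% and 29.7% did. Whether XRN4, FRY1 and SMG7 transcripts were altered in the mutant libraries was not analysed here, because contigs carry no gene names.

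The comparison of xrn4-6 with wild-type seedlings asks which decay intermediates change when XRN4 is missing. No RNA levels were used here. In every comparison a change of 5' ends on a contig can therefore come from the amount of the transcript as well as from its decay. 5' ends were higher on 232 contigs and lower on 5 of the 62802 tested, and 7715 contigs had an unadjusted p under 0.05. The largest fall was on the 882 nt contig c942, from 38.5 ± 2.67 to 0.339 ± 0.396 CPM (SD, n = 2), with a log2 change of -6.86 (SE 0.82, edgeR adjusted p = 0.0408), which was -9.21 without xrn4-6 replicate 1 and -5.93 without xrn4-6 replicate 2. Its most frequent tag was AACTTGTTTAGAGTCCTTAA. Contig c41361, with the tag TGATAATAGACTGATTCATT, was at 12.98 ± 0.882 CPM in wild type and 0.963 ± 0.0224 CPM in xrn4-6 (n = 2; edgeR adjusted p = 0.0368). The largest rises were on contig c21615, from 0.100 ± 0.141 to 12.8 ± 0.261 CPM, and contig c51742, from 0.342 ± 0.032 to 18.9 ± 12.9 CPM (n = 2). Both were also above their wild type in the other mutants. Scaled to contig reads without TMM, contig c21615 was at 7.39 and 6.37 CPM in fry1-6 and 14.03 and 17.1 CPM in smg7-1 flowers. Contig c51742 was at 12.4 and 27.5 CPM in fry1-6 and 15.7 and 19.3 CPM in smg7-1. Wild-type seedlings of 12 days held them in replicate 2 too, at 7.35 and 5.84 CPM (c21615) and 6.19 and 1.64 CPM (c51742) after mock and cycloheximide treatment, against at most 0.415 CPM in replicate 1. Whether these 2 contigs are plant transcripts was not determined here. With any 1 of the 6 libraries left out, fry1-6 libraries included, edgeR called 0 contigs in both directions, with 4282 to 8018 at an unadjusted p under 0.05. A group left with 1 library was assumed there to vary like the others. DESeq2 on all 6 libraries called 1883 higher and 231 lower. An edgeR fit with the replicate number as a block, a pairing the labels do not state, called more still, as given with the alternatives below.

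The stop codon peak, where 5' ends mark the rear edge of a ribosome waiting at the stop codon, was lower in xrn4-6 than in wild type. It held 13.1% ± 1.65 of the 5' ends in wild type and 7.26% ± 0.505 in xrn4-6 (SD, n = 2), a difference of -5.86 percentage points over 3296 contigs (two-sided exact permutation p = 0.333, the smallest possible). Both xrn4-6 libraries, at 7.61% and 6.90%, lay below both wild-type libraries, at 14.3% and 11.9%. In fry1-6 the peak was 7.58% ± 0.0556 (n = 2), a difference of -5.54 percentage points from wild type (exact permutation p = 0.333), and it differed from xrn4-6 by less than the spread between replicates (0.321 percentage points; exact permutation p = 0.667). With reads pooled over contigs the differences from wild type were -4.64 points in xrn4-6 and -4.54 points in fry1-6, and with a minimum mean of 20 reads they were -5.86 and -5.49 points. When each covered position counted once in place of its reads, which by construction weakens a peak made of reads, they were -0.780 and 0.179 points. The reading frame share was 37.2% ± 0.105 in wild type and 37.1% ± 0.203 in xrn4-6, a difference within the spread of replicates (exact permutation p = 1), and 35.6% ± 0.286 in fry1-6 (n = 2), a difference from wild type of -1.57 points (exact permutation p = 0.333) that was -0.572 points with each covered position counted once.

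**Figure D1:**
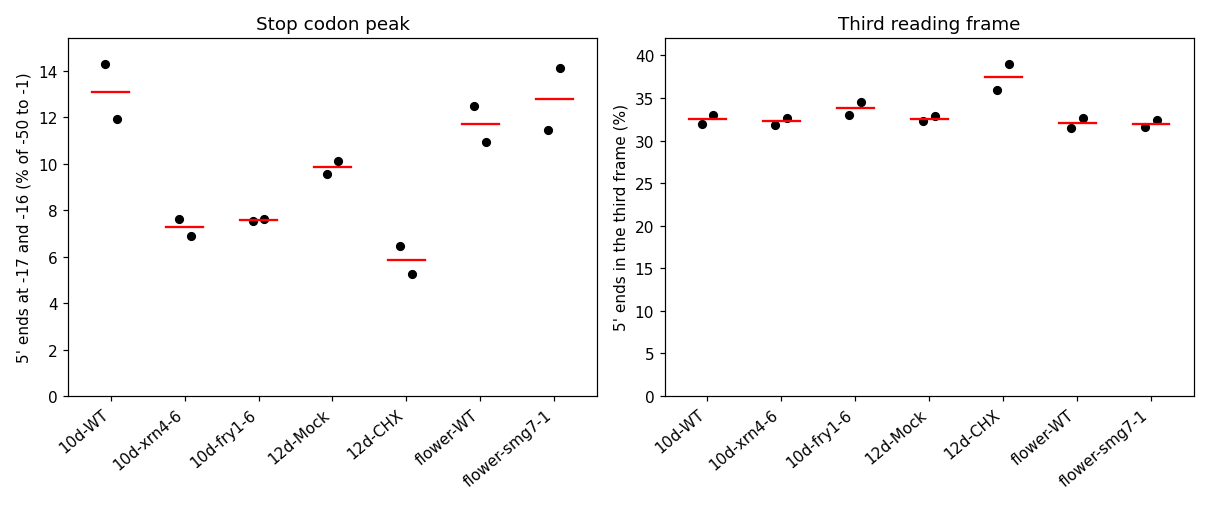
Left, the share of 5' ends at -17 and -16 among those at -50 to -1 from the stop codon (%). Right, the share of 5' ends in the third frame of open reading frames, at the last nucleotide of a codon (%). Position -17 lies in the second frame and position -16 in the third. Points are libraries and red lines are group means (n = 2). The xrn4-6, fry1-6 and cycloheximide libraries lie below their control libraries on the left, and the cycloheximide libraries, at 36.0% and 38.9%, are the highest on the right.

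**Figure D2:**
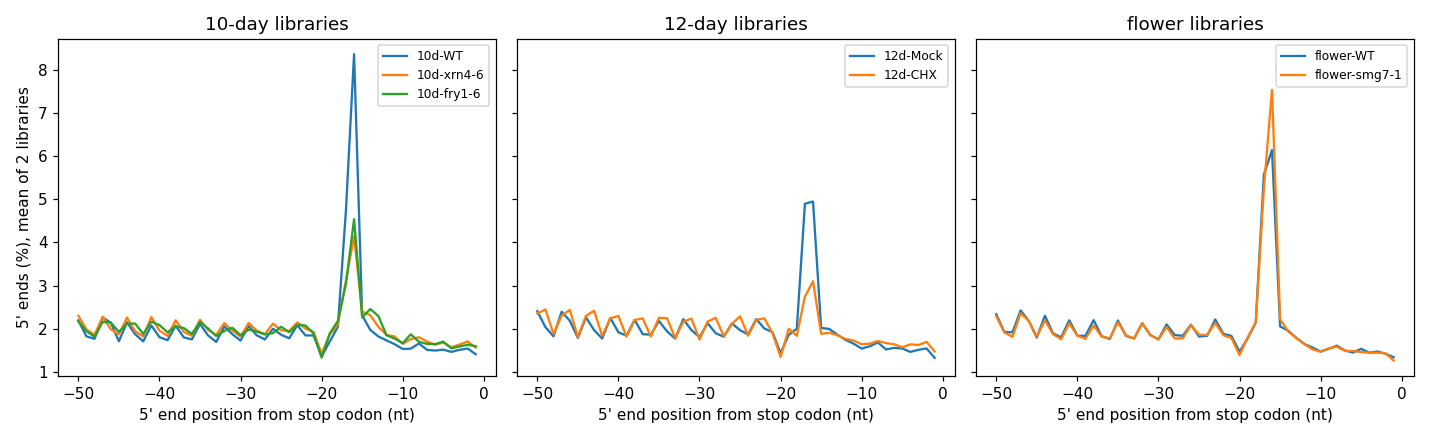
Share of 5' ends (%, mean of 2 libraries) at each position from -50 to -1 nt before the stop codon, by experiment. Lines are groups. The peak at -17 and -16 is lower in xrn4-6 and fry1-6 than in wild type, and lower after cycloheximide than after mock treatment.

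The comparison of fry1-6 with wild type asks the same question where several XRN enzymes are expected to be inhibited. Relative to the other contigs, 5' ends were higher on 10659 contigs and lower on 3297 of 62802. Contig c65082 had 0 reads in wild type and 20.3 ± 18.0 CPM in fry1-6 (SD, n = 2), at least 231.8-fold higher, and contig c50152 had 0 reads and 13.2 ± 4.09 CPM, at least 154.7-fold higher. Contig c64715, with the tag TTAAGCTGAAGAGAATTGCT, fell from 1694 ± 442 to 80.6 ± 17.05 CPM (log2 change -4.39, SE 0.37, edgeR adjusted p = 0.000649), and contig c7178, with the tag TCTCCCTCGGAGAACAGATC, fell from 15.3 ± 0.193 to 0.567 ± 0.662 CPM (n = 2). For contig c64715 the log2 change was -2.93 with capped positions but 0.21, without a call, with distinct positions, a count limited by its length of 100 nt. The split between directions depends on the scale. Scaled to all 20 and 21 nt reads, an alternative chosen after seeing the data, 4854 contigs were higher and 35554 lower, since the median contig then shifted by -1.36 on the log2 scale, and 12.0% of the calls were higher in place of 76.4%. Without wild-type replicate 1 the counts were 5037 higher and 433 lower, and without wild-type replicate 2 they were 5424 and 564. The counts of contigs lower were 1396 without fry1-6 replicate 1 and 1033 without fry1-6 replicate 2.

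Sites of miRNA cleavage held more 5' ends in fry1-6 than in wild type. Of the 56 sites tested, 35 rose and 1 fell adjusted over the list alone, and 28 rose and 1 fell over all features, with a median log2 change of 2.17 (camera p = 4.1e-10, and p = 0.0104 with an estimated correlation). The sites were kept on reads that include fry1-6, and the contigs set against them by camera were not chosen in this way. The counts and the camera p may therefore lean toward a rise. A site of miR156, a family known to target SPL transcription factor transcripts, has the tag TCTTCTGTCAGTCTCTTTTA. It rose from 31.2 ± 16.4 to 458 ± 64.9 CPM (SD, n = 2; log2 change 3.87, SE 0.45, edgeR adjusted p over the sites 5.64e-04). A miR169 site, TCTTTGGCTCATTCTCTATT, rose from 11.5 ± 1.36 to 194.8 ± 4.05 CPM, and a miR396 site, AGCTGTGGAGGAATTTCAAG, rose from 42.3 ± 8.02 to 303.6 ± 149 CPM. The miR824 site AAATGGTCTAGACATGAGAG was at 82.4 ± 0.948 CPM in wild type and 528 ± 519 CPM in fry1-6, and its edgeR adjusted p was 0.0364 over the sites, 0.0778 over all features and 0.234 over the sites when scaled to all reads. The miR160 site GAGCCAGGCAAGCTCAACAA and the miR397 site CACTCAATAAGAAACTAGAG did not pass the test, with log2 changes of 2.31 and 0.59. The site that fell, named after its values were seen, was a miR172 match of score 5, TTAAGCTTTTCCAGTTCGGG, from 2.68 ± 0.0713 to 0.968 ± 0.018 CPM. Scaled to all reads, 14 sites were higher and 3 lower, the miR156, miR169 and miR396 sites among the higher ones with log2 changes of 2.49, 2.71 and 1.43, and the median of the sites was 0.83. Without wild-type replicate 2, fry1-6 replicate 1 or fry1-6 replicate 2, 0 sites were lower.

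**Figure D3:**
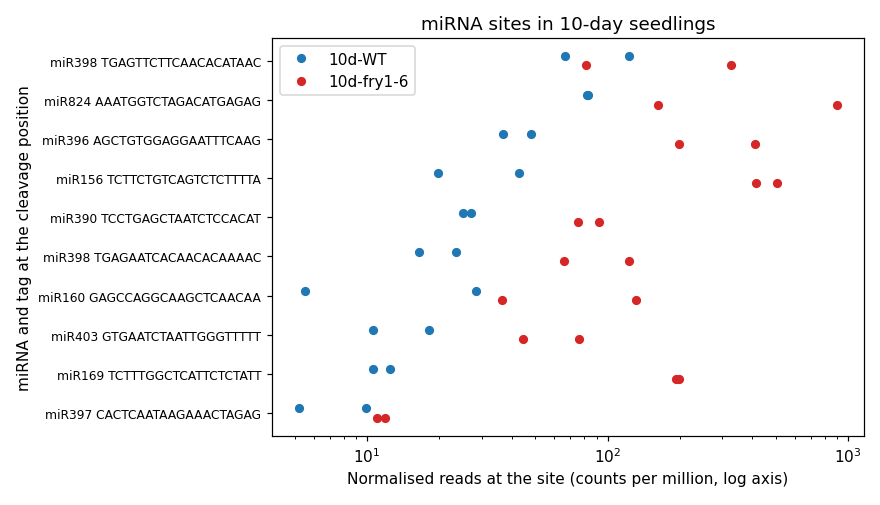
Normalised reads (CPM, log axis) at the 10 miRNA sites with the most reads in wild-type seedlings, with the miRNA and the tag at the cleavage position. Blue points are the 2 wild-type libraries and red points the 2 fry1-6 libraries. At the miR156 site fry1-6 averages 458 against 31.2 in wild type.

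In xrn4-6 no site passed the edgeR test adjusted over the list alone (0 higher and 0 lower of 56, with 9 at an unadjusted p under 0.05; DESeq2 was not run on the sites), although 39 of the 56 log2 changes were above 0 and their median was 0.62. The camera p of the list was 8.68e-04, and the call was lost at p = 0.0548 with an estimated correlation. With the replicate number as a block, a pairing the labels do not state, some sites did pass, as given with the alternatives below. The miR156 site was at 80.8 ± 13.2 CPM in xrn4-6 (n = 2; log2 change 1.37, edgeR adjusted p over the sites 0.203).

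A direct comparison of fry1-6 with xrn4-6 gave 7256 contigs higher and 1370 lower in fry1-6. Contig c24357 had 0 reads in xrn4-6 and 261 ± 71.9 CPM in fry1-6 (SD, n = 2), at least 3363-fold higher, and contig c32985 had 0 reads and 135 ± 22.2 CPM, at least 1748-fold higher. Contig c64715 was lower, at 80.6 ± 17.05 against 1054 ± 118 CPM (log2 change -2.18 with capped positions and 0.24, without a call, with distinct positions), and contig c4542 was lower, at 0.524 ± 0.047 against 10.1 ± 3.49 CPM. The miRNA sites rose at 26 of 56 and fell at 0 adjusted over the list alone, with 29 at an unadjusted p under 0.05 (camera p = 1.2e-08, and p = 0.0135 with an estimated correlation). Here too the sites were kept on reads that include fry1-6, so these values may lean toward a rise. Scaled to all reads there were 3651 contigs higher and 39511 lower, which turned the split from 84.1% to 8.46% of calls higher, and 10 sites were higher and 6 lower, with a median log2 change of the sites of -0.17 in place of 1.25. Without xrn4-6 replicate 1 the counts were 3921 higher and 269 lower. Contigs lower were 540 without xrn4-6 replicate 2, 487 and 506 without wild-type replicates 1 and 2, and 729 and 192 without fry1-6 replicates 1 and 2.

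Among contigs tested in both mutants, 213 were higher in both against wild type and 3 lower in both, where independent lists of the same sizes would share 39.4 and 0.262. Across contigs, which are not independent replicates, the log2 changes had a correlation of 0.323, below the 0.473 that 5 simulations of unchanged groups against the shared wild-type libraries gave. The covariance was 0.358 against a simulated 0.141, a difference of 0.217. These simulations gave 0 contigs higher in both, since unchanged groups leave few calls to share. That 0 is therefore no reference for the 213. The 39.4 leaves out the shared wild-type libraries, and how far they raise the overlap was not determined. With 1 wild-type library for each mutant the correlation was 0.208 or 0.235.

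Cycloheximide asks how blocking translation changes 5' ends. It was the comparison with the most calls. Relative to other contigs, 17243 were higher and 15422 lower of 63936, 51.1% of those tested. Contig c55339 had 0 reads after mock treatment and 29.6 ± 9.34 CPM after cycloheximide (SD, n = 2), at least 330.1-fold higher, and contig c28281 had 0 reads and 28.2 ± 4.27 CPM, at least 318-fold higher. Contigs c58610 and c33913 were lower, at 0.123 ± 0.098 against 10.4 ± 3.42 CPM and at 0.225 ± 0.090 against 18.3 ± 12.9 CPM. Scaled to all 20 and 21 nt reads, 10183 contigs were higher and 35477 lower, 22.3% of calls higher in place of 52.8%, with the median contig shifted by -1.04 on the log2 scale.

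The stop codon peak was 9.84% ± 0.389 after mock treatment and 5.84% ± 0.854 after cycloheximide (SD, n = 2), a difference of -4.00 percentage points over 3333 contigs (exact permutation p = 0.333). With each covered position counted once the difference was -0.323 points. The reading frame share was 37.1% ± 0.00568 after mock treatment and 35.4% ± 0.663 after cycloheximide, a difference of -1.72 points (exact permutation p = 0.333) that was -0.478 points with each covered position counted once and -2.23 points with reads pooled over contigs. Of the miRNA sites, 16 rose and 21 fell of 54 adjusted over the list alone, and the same numbers over all features (camera p = 0.212, and p = 0.599 with an estimated correlation). The sites were kept on reads that include cycloheximide, so a site high only there could be kept for that reason. The number that rose and the camera p may therefore lean toward a rise. The miR156 site TCTTCTGTCAGTCTCTTTTA fell from 21.8 ± 3.19 to 2.63 ± 0.384 CPM (n = 2; log2 change -3.05, SE 0.32). The miR160 site GAGCCAGGCAAGCTCAACAA, the miR403 site GTGAATCTAATTGGGTTTTT, the miR169 site TCTTTGGCTCATTCTCTATT and the miR390 site TCCTGAGCTAATCTCCACAT also fell, with log2 changes of -2.103, -2.29, -1.91 and -1.16. Matches of 1 miRNA did not all move alike, as other sites named after their values were seen show. The miR390 matches TCCTGAGCTCGGGACTCTCT and TTCTGAGCTTGGAAATCTGA rose, with log2 changes of 5.74 and 1.07, of which the second was 0.03 when scaled to all reads, and the miR156 match TCTTCCGTCGGCCTTTATGA rose with 3.26. Of the 39 reads of the first, 22 and 14 were from the 2 cycloheximide libraries. This miR156 match and the miR390 site that fell have a score of 5, where some sites are chance matches. The contrast therefore need not concern 1 miRNA. The miR169 match TTCTTGGCTTTTTCGTTTTT did not pass the test, with a log2 change of 0.15. In the other direction a miR398 match of score 5, TGAGTTCTTCAACACATAAC, rose from 10.8 ± 8.49 to 2212 ± 2053 CPM, with values of 760 and 3663 CPM in the 2 cycloheximide libraries. Scaled to all reads, 11 sites were higher and 33 lower.

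Flowers of smg7-1 ask which 5' ends change when SMG7 is disrupted. Few contigs were called in the planned fit: 33 higher and 86 lower of 61684, with 3664 at an unadjusted p under 0.05. With the replicate number as a block, a pairing the labels do not state, far more were called, as given with the alternatives below. Contigs c12482 and c54099 were at 40.1 ± 16.7 and 33.3 ± 13.8 CPM in wild type (SD, n = 2) and had 0 reads in smg7-1, at least 625-fold and 519-fold lower. Contig c9180 was at 0.076 ± 0.108 CPM in wild type and 56.5 ± 25.2 CPM in smg7-1, and contig c6385 at 0.267 ± 0.234 and 31.1 ± 2.46 CPM. Both were also high in the seedling mutants. Scaled to contig reads without TMM, contig c9180 was at 17.63 and 31.9 CPM in xrn4-6 and 60.2 and 108 CPM in fry1-6, and contig c6385 at 27.6 and 31.5 CPM in xrn4-6 and 46.5 and 50.1 CPM in fry1-6. Contig c6385 was also at 7.19 and 4.76 CPM in replicate 2 of the mock and cycloheximide seedlings. Whether they are plant transcripts was not determined either. The simulated share of false calls was 21.2% in this design. With 20-mers in at least 3 libraries the calls were 7 higher and 5 lower, and with open-frame contigs only, which are fewer, 0 and 0 (545 at an unadjusted p under 0.05). The rule of 3 libraries by construction drops sequence held by the 2 wild-type flower libraries alone. The planned fit called 12 open-frame contigs higher and 6 lower. DESeq2 called 473 higher and 220 lower, and the fit without smg7-1 replicate 2 called 1358 higher and 318 lower. The fit without smg7-1 replicate 1 called 559 and 242, and that without wild-type replicate 1 called 82 and 138.

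The stop codon peak of flowers was 11.7% ± 1.07 in wild type and 12.8% ± 1.90 in smg7-1 (SD, n = 2), a difference of 1.07 percentage points that was smaller than the spread between replicates (exact permutation p = 0.667). The reading frame share was 37.2% ± 0.419 and 37.1% ± 0.0311 (exact permutation p = 1). Of the 46 miRNA sites, 0 were higher and 1 lower by edgeR adjusted over the list alone, 5 had an unadjusted p under 0.05, and over all features 0 were called. The lower site, named after its values were seen, was the miR172 match TTAAGCTTTTCCAGTTCGGG, at 2.28 ± 0.438 CPM in wild type and 0.0803 ± 0.0503 CPM in smg7-1. As a list the sites did not differ from other features (camera p = 0.298, and p = 0.693 with an estimated correlation).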

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

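Of the tests here, the one of read errors was chosen after the result was seen. In fry1-6, 64.6% and 70.3% of the reads (replicates 1 and 2) lay outside the contigs, against 40.8% and 47.1% in the 2 wild-type libraries, so reads outside the contigs of 100 nt or more, of which only those at miRNA sites on shorter contigs were tested, made up more of these libraries than of their controls. One candidate explanation was RNA that only fry1-6 holds. 20-mers found in both libraries of a group and in no other group took 6.03% and 7.49% of the fry1-6 reads. After cycloheximide they took 5.48% and 5.33%, so the lower fry1-6 library was 0.552 percentage points above the highest other library. They were counted whether or not they lay on contigs, so the count does not measure reads outside the contigs. Even if all lay outside, the fry1-6 shares would be smaller than the excess over the 2 wild-type libraries. In wild type such 20-mers took 0.156% and 0.129%. As 1 read in any library of another group removes a 20-mer from this count, the count cannot decide on RNA that is much higher in fry1-6 but leaves traces elsewhere. Read errors were the other: 20-mers of 1 library or taken as errors gave a difference of -0.838 points by the same measure. This class also holds 20-mers that only 1 fry1-6 library has. The values argue against read errors of this kind, and against 20-mers held by both fry1-6 libraries and no other group, as the whole cause. They draw no conclusion on RNA much higher in fry1-6. Reads in repeated or abundant RNA that does not assemble into contigs of 100 nt stay open and were not tested, and as a result the fold changes of fry1-6 are relative to the contigs that did assemble.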

How the results depend on the processing

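Alternatives chosen after seeing the data were the assembly from 20-mers in at least 3 libraries, contigs with open frames only, a miRNA score of 4 or less, tags whose first 10 nt pair with a miRNA, and scaling to all 20 and 21 nt reads. Where leaving out 1 library left 1 in a group, that library was assumed to vary like the other groups. Unless said otherwise the cause of a difference was not tested. Contigs with open frames only, and stricter miRNA rules, test fewer features by construction. On open-frame contigs the main fits called 10 higher and 3 lower for xrn4-6, and 917 and 826 for fry1-6 against wild type. They called 571 and 300 for fry1-6 against xrn4-6, 2693 and 2763 for cycloheximide, and 12 and 6 for smg7-1. Of the rises against wild type, 9742 of 10659 in fry1-6 and 222 of 232 in xrn4-6 were on other contigs. These were 52798 of the 62802 tested. Distinct positions count an often-read position once, which by construction weakens a peak made of reads. Without a filter on low counts no count of contigs moved by over 1.5 times. Alternatives that concern exon junctions and gene lists were not run, as they need gene models. Where few features change, a small fold change stays out of reach: in such simulations 0% to 2% of 2-fold changes were called. These shares do not carry over to comparisons with many calls. For cycloheximide, miRNA sites with log2 changes of 1.07 and -1.16 passed the threshold in the main fit.

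For xrn4-6 against wild type, contigs higher and lower (232 and 5) became 1883 and 231 with DESeq2, 1896 and 104 in one fit of all 14 libraries, 1 and 0 with distinct positions (4634 at an unadjusted p under 0.05), 0 and 0 with capped positions (7133), 14 and 2 with 20-mers in at least 3 libraries, and 0 and 0 with open-frame contigs (1114). Contigs lower were 8 scaled to all reads. Leaving out 1 library gave 0 to 0 in both directions. For fry1-6 against wild type (10659 and 3297), contigs lower were 4980 in the fit of 14 libraries, open frames gave 1141 and 420, all-read scaling gave 4854 and 35554, and leaving out 1 library gave 5037 to 10032 higher and 433 to 2635 lower. For fry1-6 against xrn4-6 (7256 and 1370), contigs lower were 2801 in the fit of 14 libraries and 2150 with distinct positions, open frames gave 628 and 128, all-read scaling gave 3651 and 39511, and leaving out 1 library gave 3921 to 6258 higher and 192 to 729 lower. Contig c64715 turned to 0.21 and 0.24 on the log2 scale against wild type and xrn4-6 with distinct positions, a count that is relative to the positions covered on other contigs and limited by its length of 100 nt. With capped positions it was -2.93 and -2.18. For cycloheximide (17243 and 15422), open frames gave 2893 and 2619 and all-read scaling gave 10183 and 35477. Leaving out 1 library gave 15091 to 16233 higher and 11069 to 14072 lower. For smg7-1 (33 and 86), DESeq2 gave 473 and 220, the fit of 14 libraries 111 and 149, 20-mers in at least 3 libraries 7 and 5, open frames 0 and 0 (545 at an unadjusted p under 0.05), and leaving out 1 library 41 to 1358 higher and 113 to 318 lower.

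Among named contigs, leaving out 1 library gave log2 changes of -9.21 to -5.93 for c942, 4.83 to 6.33 for c51742, -7.21 to -3.87 for c7178, -7.46 to -5.71 for c58610, -6.88 to -5.30 for c33913 and 6.15 to 8.17 for c6385 in flowers. They were 5.95 to 11.16 for c21615, 10.58 to 12.67 for c65082 and 8.47 to 13.34 for c9180, whose control groups held few or 0 reads, so the size of the fitted change is uncertain. With any 1 library left out, none of the 4 contigs named for xrn4-6 against wild type passed the threshold.

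With the replicate number as a block, contigs higher and lower were 6733 and 3030 for xrn4-6, 17147 and 13506 for fry1-6 against wild type, 14022 and 11030 for fry1-6 against xrn4-6, and 3429 and 1875 for smg7-1. Sites higher and lower were 14 and 1 for xrn4-6 and 6 and 5 for smg7-1, and 2 sites were lower in fry1-6 against xrn4-6. Libraries with replicate number 1 deviated together, with correlations of 0.677, 0.546 and 0.630 between the 10-day groups, 0.298 between the 12-day groups and 0.623 between the flower groups. With 2 numbers only, the design does not show that the numbers pair the libraries.

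Of miRNA sites, first 10 nt paired with at least 1000 reads gave 2 higher in xrn4-6. For fry1-6 against wild type (35 higher, 1 lower), score 3 or less gave 7 and 0, score 4 or less 18 and 0, first 10 nt paired 3 lower at both 300 and 100 reads and 22 higher at 1000, all-read scaling 14 and 3, and leaving out 1 library 24 to 37 higher and 0 to 1 lower. For fry1-6 against xrn4-6 (26 and 0), score 3 or less gave 5 higher, score 4 or less 13 higher, first 10 nt paired 4, 4 and 1 lower at 300, 100 and 1000 reads, and all-read scaling 10 and 6. For cycloheximide (16 and 21), score 3 or less gave 2 and 6, score 4 or less 7 and 10, first 10 nt paired 5 higher at 300 reads, 35 lower at 100 and 3 higher at 1000, and all-read scaling 33 lower. For smg7-1 (0 and 1) the stricter scores and the paired tags left 0 lower, and leaving out 1 library gave 0 to 2 higher and 1 to 2 lower. The camera p of the list was 0.0548 with an estimated correlation in xrn4-6. Leaving out 1 library it ran from 0.0489 (without cycloheximide replicate 2) to 0.377 for cycloheximide and from 0.0168 (without wild-type replicate 2) to 0.844 for smg7-1. For smg7-1 the direction turned without wild-type replicate 1 (0.284) and without smg7-1 replicate 2 (0.844).

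With distinct positions the stop codon peak differed by -0.780 (xrn4-6), 0.179 (fry1-6), 0.959 (fry1-6 against xrn4-6), -0.323 (cycloheximide) and -0.297 (smg7-1) percentage points, and the reading frame share by -0.572 (fry1-6), -0.471 (fry1-6 against xrn4-6) and -0.478 (cycloheximide). With reads pooled over contigs the frame difference was 0.0241 for xrn4-6 and -2.23 for cycloheximide, and with 20-mers in at least 3 libraries it was 0.0721 for xrn4-6. Leaving out 1 library gave stop codon differences of -0.0359 to 0.679 for fry1-6 against xrn4-6 and -0.271 to 2.42 for smg7-1, and frame differences of -0.210 to 0.0776 for xrn4-6 and -0.414 to 0.179 for smg7-1. The directions of the stop codon differences of xrn4-6, fry1-6 and cycloheximide held without any 1 library, at -7.03 to -4.69, -6.71 to -4.37 and -4.60 to -3.40 points.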

Other observations

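The count of contigs absent from seedlings was chosen after the results were seen. The 86 contigs lower in smg7-1 flowers were mostly absent from seedlings. Of them 58 (67.4%) were under 1 CPM in all 10 seedling libraries, against 1637 of the 61684 contigs tested (2.65%) and 0 of the 33 contigs higher in smg7-1. A tag held by 2 libraries could enter the assembly, so sequence of the 2 wild-type flower libraries alone can form contigs. Such contigs are low in smg7-1 and in seedlings by construction, so the 2.65% is no matched background. How many of the 58 are of this kind was not determined. With tags in at least 3 libraries 5 contigs were lower in smg7-1, and with open-frame contigs only, which are fewer, 0. The rule of 3 libraries bars tags held by the 2 wild-type flower libraries alone, also where a transcript was truly lost in smg7-1. The fall to 5 therefore does not tell whether the 86 calls are false. Of the 86, 6 were on open-frame contigs. The simulated share of false calls for flowers was 21.2%. Of the contigs with 5 CPM or more in both wild-type flower libraries, 39, spanning 6271 nt, had at most 3 reads over both smg7-1 libraries. In the opposite direction there were 2. After cycloheximide 144 contigs of this kind were present that had at most 3 reads after mock treatment, and 4 were lost.

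After cycloheximide the third frame of open reading frames gained 5' ends, with 37.5% ± 2.11 against 32.6% ± 0.381 after mock treatment (SD, n = 2; difference 4.89 percentage points, exact permutation p = 0.333). A preference for certain bases at the tag's 5' end was a candidate explanation. At equal first 2 bases the difference was 5.39 points against 5.83 without matching, with both cycloheximide libraries (35.9% and 39.5%) above both mock libraries (32.1% and 32.5%). These values argue against that as the whole cause. The third-frame share was higher after cycloheximide on 84.1% of 10040 contigs. An effect of cycloheximide on where ribosomes stop stays open as a hypothesis that was not tested.

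The stop codon peak was lower than in wild type on 81.6% of 3187 contigs in xrn4-6 and on 77.4% of 2661 contigs in fry1-6. Over contigs with 20 reads or more at -50 to -1 in each 10-day library, drawn down to 20 reads, the peak was 13.4% and 11.2% in wild type, 7.42% and 6.84% in xrn4-6 and 7.29% and 7.38% in fry1-6. Drawing reads at random does not move an expected share, so these values are no test of read depth. The reason for the difference stays open.

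4 contigs were higher in both xrn4-6 and smg7-1, among them c6385, c7464 and c21615. Scaled to the contig reads of each library without TMM, contig c6385 was at most 0.816 CPM in the 10-day wild-type and the wild-type flower libraries. In the 12-day libraries it was at 0.415 and 0.138 CPM in replicate 1 and at 7.19 and 4.76 CPM in replicate 2 of mock and cycloheximide. Contig c7464 was at 24.0 and 20.01 CPM in xrn4-6, 10.7 and 7.44 CPM in fry1-6 and 17.41 and 19.3 CPM in smg7-1. Contig c9180, which was high in the same 3 lines, was at most 0.164 CPM in the 12-day libraries. Vector DNA of the mutant lines is an open explanation for these contigs, with carry-over between libraries for the levels in 12-day replicate 2. Neither was tested, as no vector sequence was used here.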
